A study of Mus musculus with 6 samples.

How the data were processed

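The series measured microRNAs (miRNAs) by small RNA sequencing in the trigeminal ganglion, the sensory ganglion of the face and the cornea, of C57BL/6J mice. Per the labels, 3 libraries came from normal mice (replicates 2, 3 and 4) and 3 from diabetic mice (replicates 1, 3 and 4). Diabetes was induced, per the labels' protocols, with intraperitoneal streptozotocin, a toxin of the insulin-producing beta cells, at 50 mg/kg for 5 days, and blood glucose was then measured every 4 weeks. The age of the mice and the duration of diabetes at dissection were not given in the sources used here. The labels name no pooling and do not say that each library came from a separate animal, so the p-values measure only the spread between these libraries, which may be partly technical.

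Per the labels' protocols, RNA was extracted with TRIzol, libraries were made from 1 µg of total RNA with NEBNext small RNA reagents, and PCR products of 135 to 155 bp, corresponding to inserts of 15 to 35 nt, were selected. The authors' deposited table held whole-number read counts for each mature miRNA and precursor, not normalized. Per the submitters' processing notes, cutadapt and Bowtie were among the tools used. The genome build, the miRNA annotation, the treatment of reads that match several precursors and any filter on low counts were not given in the sources used here.

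The table held 672 rows for 574 mature miRNA names. Of these names, 50 stood on more than 1 row, 1 for each precursor copy. Counts were identical between the copies of 20 names and differed for 30. Copies were not summed, since that would count reads more than once where a read had been assigned to each copy. For each mature miRNA the copy with the highest total was kept, and 16 differently named miRNAs that shared identical counts in 7 groups were joined, which left 565 miRNAs. The joined rows and close paralogs are uncertain, since reads can match more than 1 of them. Among such paralogs are miR-378a, b and c, miR-486a and b, miR-133a and b, miR-146a and b, and the let-7 and miR-30 members. Library totals after this step ranged from 4373085 to 6156664 counts. The lowest total of a miRNA over the 6 libraries was 27 counts and 1 value of the whole table was 0, and whether low miRNAs had been removed before deposit was not given in the sources used here. The totals are those of the listed miRNAs alone.

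Counts were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust estimation, TMM scaling, group as the sole term, no pairing), after the default expression filter with a minimum count of 10, which kept 520 miRNAs and removed 45. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05 on the adjusted value. Levels are TMM-scaled CPM with the SD over 3 libraries, and fold changes are diabetic over normal. The standard error (SE) of a log2 fold change was its size divided by the square root of F. The common dispersion was 0.0722, a biological coefficient of variation of 26.9%.

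Before the data were examined, 23 lists of miRNAs were fixed: neuronal, sensory miR-183 cluster, myelinating glia, leukocyte, inflammation-induced, erythroid, striated muscle, endothelial, fibroblast and smooth muscle, epithelial, endocrine, nerve injury, diabetic neuropathy literature, hypoxia, the let-7, miR-29, miR-30, miR-34 with miR-449, miR-181, and miR-15 with miR-16, miR-195 and miR-497 families, the miR-17~92 and paralog clusters, the imprinted Dlk1-Dio3 cluster and the Sfmbt2-intron repeat cluster. The 21 lists with 3 or more tested members were compared with all other miRNAs by camera of limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether the members of a list move on balance in 1 direction and does not compare them with other miRNAs, was run beside it. The adjusted p-values of lists are over the 21 lists. Shares of counts per list were compared by exact two-sided permutation tests of 3 against 3 libraries, which cannot give a p below 0.1.

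The rule for the miRNAs named in the text was also fixed before the data were examined. It took, in each direction, the 8 with the smallest p where fewer had passed the threshold, the 5 most abundant miRNAs, and up to 4 members of each list with the smallest p. Some miRNAs fall outside the rule and were chosen after their values were seen. They are miR-182-5p, miR-155-5p, miR-1298-5p, miR-1a-3p, miR-7a-1-3p, miR-144-5p, miR-486a-3p, miR-219a-2-3p, miR-493-5p, miR-221-3p, miR-222-3p, miR-30b, miR-30c-5p and the 3p arms of miR-30 members. Alternatives fixed at the same time were DESeq2 1.42.0, limma-voom, other scalings (DESeq2 size factors, library totals, upper quartile), other count filters, omission of the 3 most abundant miRNAs, an unadjusted threshold with a fold of 1.5, omission of each library in turn and the replicate number as a block. Other handling of the precursor copies, edgeR without robust estimation and shorter erythroid and let-7 lists were added after the data were seen. The shorter erythroid list left out the near-identical miR-486b miRNAs. The shorter let-7 list kept only the 5p arms of let-7a to let-7g and let-7i. A term for a grouping of the libraries read from their own values was explored and is not reported, since such groups are defined by the outcome.

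The test was checked on 20 simulated data sets of 565 miRNAs with the means and library sizes of this comparison and 200 changed miRNAs each. It recovered 18.2% of the 1.5-fold, 59.6% of the 2-fold and 99% of the 4-fold changes, and 2.31% of its calls were false. Each simulated miRNA was drawn independently with the same dispersion of 0.0722, so these rates may not carry over to the real libraries. Pairs of libraries of the same group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 128, so none was counted as a duplicate. Genomic positions of the precursors are those of the GENCODE mouse annotation on GRCm38, 1-based. Since PCR reads carried no molecular identifiers, the 95% Wilson intervals of single libraries cover counting error only. Figures were drawn with matplotlib 3.10.9.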

Results

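The trigeminal ganglion holds the cell bodies of the sensory neurons that supply the face and the cornea. Its miRNAs were profiled in 3 libraries from normal and 3 from streptozotocin-diabetic C57BL/6J mice, to find those whose levels differ in diabetes. Library totals were 6156664, 4373085 and 4387314 counts for normal replicates 2, 3 and 4, and 5565780, 4972716 and 5398428 for diabetic replicates 1, 3 and 4. The 5 most abundant miRNAs were miR-99a-5p, let-7f-5p, miR-27b-3p, miR-30a-5p and miR-26a-5p, with 9.10%, 7.68%, 7.36%, 6.68% and 5.53% of counts over the 6 libraries. The sensory cluster miRNAs miR-183-5p and miR-182-5p followed among the 10 most abundant, with 4.70% and 4.32%.

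In diabetic ganglia miR-146a-5p, a miRNA induced by NF-kB that restrains inflammatory signalling, was at 5199 ± 237 CPM (SD, n = 3) against 2539 ± 267 CPM in normal ganglia. This 2.05-fold difference (95% interval 1.59 to 2.63) had the smallest p of all miRNAs, and its paralog miR-146b-5p was at 2390 ± 209 against 1270 ± 228 CPM (1.88-fold). The nerve-injury miRNA miR-31-5p was 1.94-fold higher, and miR-148a-3p and miR-30a-5p, both among the 10 most abundant miRNAs, were 1.89-fold and 1.80-fold higher in the diabetic libraries. Of the miRNAs with lower values, the muscle miRNA miR-133b-3p had the smallest p, at 37.4 ± 5.73 against 68.5 ± 11.9 CPM (0.545-fold), and its paralog miR-133a-3p was at 0.647-fold. None of these differences passed the adjusted threshold in edgeR.

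With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 520 miRNAs were higher and 0 were lower in diabetic ganglia. At an unadjusted p under 0.05 there were 55, of which 36 were higher and 19 lower, where chance alone would give 26 on average. Another split of the same libraries gave 67, so the excess over 26 cannot be credited to the groups. Without normal replicate 3 there were 104 (68 higher and 36 lower). DESeq2 called 10 higher and 1 lower. Its filter left the adjusted p of many of the 520 miRNAs undefined, so it adjusted over fewer miRNAs than edgeR. In limma-voom there were 0 calls in either direction, with a smallest adjusted p of 0.0556. The 10 called higher by DESeq2 were miR-146a-5p, miR-146b-5p, miR-31-5p, miR-148a-3p, miR-378a-3p, miR-378b, miR-378c, miR-144-3p, miR-200a-5p and miR-1298-5p, and the 1 called lower was miR-133b-3p; miR-1298-5p was named after its values were seen. Of these DESeq2 calls, miR-1298-5p, miR-133b-3p, miR-378a-3p and miR-144-3p lay just under the threshold (DESeq2 adjusted p = 0.0495, 0.0495, 0.0495 and 0.0496). With miRNAs of a mean of 100 counts or more alone, edgeR called miR-146a-5p (adjusted p = 0.0484).

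The log2 fold change of miR-146a-5p was 1.03 (SE 0.16, edgeR adjusted p = 0.0678), and its level was higher in every diabetic library than in every normal one. Its precursor lies on chromosome 11 from 43374397 to 43374461 of GRCm38, outside annotated host genes. For miR-146b-5p, from an intron of Mfsd13a on chromosome 19 (46342762 to 46342870), the log2 fold change was 0.91 (SE 0.19, edgeR adjusted p = 0.128). The values of miR-31-5p were low but tight, at 62.6 ± 1.54 CPM in diabetic and 32.2 ± 2.02 CPM in normal ganglia (log2 fold change 0.96, SE 0.19, edgeR adjusted p = 0.128). Its precursor overlaps an exon of a long non-coding RNA on chromosome 4 (88910557 to 88910662). The abundant miR-148a-3p was at 62240 ± 16590 CPM in diabetic and 32920 ± 813 CPM in normal ganglia, so its spread was much wider in diabetic libraries (log2 fold change 0.92, SE 0.20).

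The 3 miR-378 miRNAs among the 8 with the smallest p in this direction have near-identical sequences, so their values are uncertain and not independent of each other. miR-378a-3p, encoded in an intron of the mitochondrial coactivator gene Ppargc1b on chromosome 18 (61397835 to 61397900), was at 4862 ± 842 CPM in diabetic and 2794 ± 205.5 CPM in normal ganglia (1.74-fold). The less abundant miR-378b and miR-378c were 1.90-fold and 1.96-fold higher. Log2 fold changes of these 3 miRNAs lay between 0.80 and 0.97, each with an edgeR adjusted p of 0.128.

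**Figure D1:**
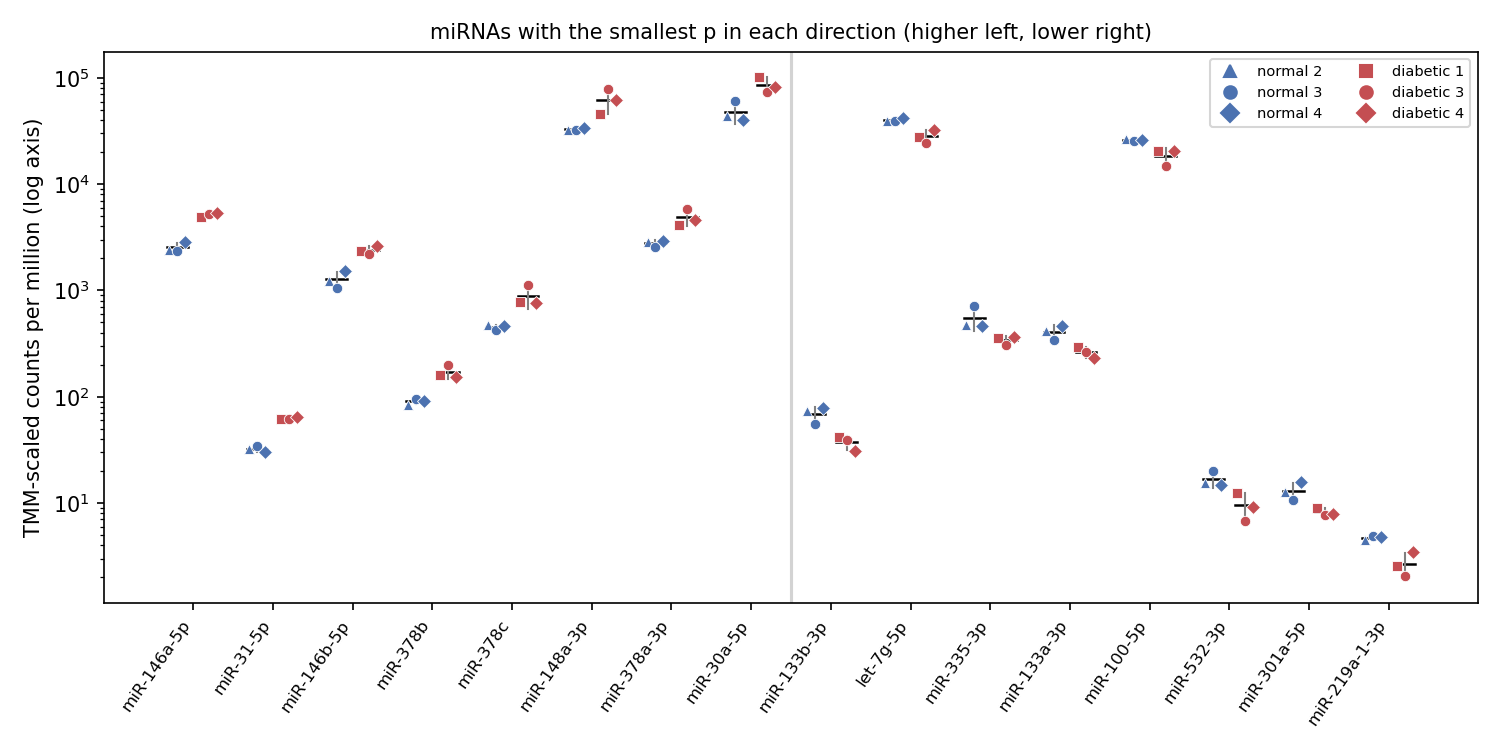
TMM-scaled CPM (log axis) of the 8 miRNAs with the smallest p in each direction, with a point per library, the group mean as a bar and the SD as a line. Each of the 16 has no overlap between the 3 normal and the 3 diabetic libraries, and miR-146a-5p has means of 2539 and 5199.

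Among the miRNAs with lower values in diabetic ganglia, let-7g-5p was at 28120 ± 3897 against 40320 ± 1455 CPM (0.697-fold, edgeR adjusted p = 0.245) and miR-100-5p at 18590 ± 3315 against 26110 ± 514 CPM (0.712-fold). miR-335-3p, from an intron of the imprinted gene Mest on chromosome 6 (30741299 to 30741396), had a log2 fold change of -0.70 (SE 0.23). The remaining miRNAs named in this direction were miR-532-3p, miR-301a-5p and miR-219a-1-3p, all at 20.1 CPM or less in each library, with log2 fold changes of -0.81, -0.67 and -0.80. Of all 520 miRNAs, 92 (17.7%) had no overlap between the groups, 45 higher and 47 lower in diabetic ganglia. Chance gives 10% on average for 3 against 3, and the miRNAs are not independent.

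The inflammation-induced list rose as a set in diabetic ganglia by camera with the preset correlation. All 5 tested members had positive log2 fold changes with a mean of 0.66, and the list passed the camera test (adjusted p = 0.00835; adjusted p = 0.552 with an estimated correlation). No member passed the threshold over all miRNAs in edgeR, where DESeq2 called miR-146a-5p and miR-146b-5p and edgeR at a mean of 100 counts or more called miR-146a-5p, and 2 did in edgeR when adjusted over the list alone, miR-146a-5p (adjusted p = 0.000652) and miR-146b-5p (adjusted p = 0.00276). The other members, miR-21a-5p, miR-155-5p and miR-146b-3p, had log2 fold changes of 0.36, 0.11 and 0.91. For miR-21a-5p and miR-155-5p the unadjusted edgeR p was 0.176 and 0.707. miR-146a-5p and miR-146b-5p are close paralogs, and miR-146b-3p is the other arm of the miR-146b precursor. These miR-146 members are not independent of each other, and the list was not tested without them. By fry, the inflammation-induced list was the 1 list past the threshold in a single direction (adjusted p = 0.0227). The leukocyte list, by contrast, did not pass (mean 0.32, camera adjusted p = 0.496), with miR-142a-3p at 0.96, miR-223-5p at 0.73, miR-142a-5p at 0.70 (1.38 without normal replicate 3) and miR-150-5p at -0.36.

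The epithelial list, with the miR-200 family, which maintains epithelial identity, rose as a set by camera with the preset correlation (adjusted p = 0.00382). It did not pass with the estimated correlation of 0.719 between its members (adjusted p = 0.718) or by fry (adjusted p = 0.424). Several members are arms of the same precursor and are not independent of each other. All 9 tested members were positive with a mean log2 fold change of 0.81, and in edgeR 0 passed over all miRNAs or adjusted over the list alone, while DESeq2 called miR-200a-5p over all miRNAs (adjusted p = 0.0171). miR-200b-3p was at 1186 ± 190 CPM in diabetic and 536 ± 273 CPM in normal ganglia, miR-200a-5p at 65.1 ± 33.3 against 21.3 ± 10.2 CPM, and miR-200b-5p and miR-429-3p had log2 fold changes of 1.35 and 0.93. The library of normal replicate 4 was the lowest in all of these, with 228 CPM of miR-200b-3p, and without it the list still passed (camera adjusted p = 0.0284).

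The erythroid list rose as a set by camera with the preset correlation (adjusted p = 0.0193). It did not pass with an estimated correlation (adjusted p = 0.718) or by fry (adjusted p = 0.388). All 7 members were positive with a mean log2 fold change of 0.87. In edgeR 0 members passed the threshold over all miRNAs or adjusted over the list alone. DESeq2 called miR-144-3p over all miRNAs (adjusted p = 0.0496). Its most abundant member, miR-451a, a miRNA of red blood cells, was at 4230 ± 2771 CPM in diabetic and 1643 ± 1336 CPM in normal ganglia. miR-144-3p, from the same cluster, had a log2 fold change of 1.52 (SE 0.52; 2.18 without normal replicate 3), and miR-486a-5p and miR-486b-5p had 0.91 and 0.90. The levels of miR-451a differed widely within each group, from 1576 to 7104 CPM in diabetic and from 798 to 3184 CPM in normal libraries. They were lower in each of normal 2, normal 4 and diabetic 3 (798, 947 and 1576 CPM) than in each of normal 3, diabetic 1 and diabetic 4 (3184, 7104 and 4009 CPM), as were those of miR-486a-5p, so the list moved with these libraries as well as with the groups. Without normal replicate 2, normal replicate 4 or diabetic replicate 1 the list no longer passed (camera adjusted p = 0.0703, 0.120 and 0.190), nor did it with near-identical members removed (0.0554).

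The nerve injury list rose as a set by camera with a p close to the threshold (adjusted p = 0.0443). It did not pass with an estimated correlation (adjusted p = 0.718) or by fry (adjusted p = 0.388). All 8 tested members were positive with a mean log2 fold change of 0.38, and 1, miR-31-5p, passed when adjusted over the list alone (adjusted p = 0.00688) against 0 over all miRNAs in edgeR, where DESeq2 called it (adjusted p = 0.0171). Of the other members, those with the smallest p, miR-21a-5p, miR-431-5p and miR-221-5p, had log2 fold changes of 0.36, 0.52 and 0.26. miR-221-3p and miR-222-3p had 0.07 and 0.13. The list's share of counts was lower in each of normal 2, normal 4 and diabetic 3 (0.730%, 0.658% and 0.911%). In normal 3, diabetic 1 and diabetic 4 it was 1.165%, 1.084% and 1.102%. The list no longer passed without normal replicate 2, normal replicate 4 or diabetic replicate 3 (camera adjusted p = 0.426, 0.120 and 0.266), or without a count filter (0.105). With the shorter erythroid and let-7 lists its adjusted p was 0.0554. Its own members were unchanged there, and only the adjustment over lists moved.

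The let-7 family fell as a set by camera with the preset correlation (adjusted p = 0.0154). It did not pass with an estimated correlation (adjusted p = 0.718) or by fry (adjusted p = 0.388). Of 19 tested members 16 were negative, with a mean log2 fold change of -0.19, and in edgeR 0 passed over all miRNAs or adjusted over the list alone. let-7g-5p, let-7j, let-7i-5p and let-7e-3p had the smallest p, with log2 fold changes of -0.52, -0.48, -0.40 and -0.39, while let-7f-5p, the most abundant member, had 0.05. The family took 17.2% ± 1.66 of counts in diabetic and 20.6% ± 2.19 in normal ganglia (exact permutation p = 0.2, adjusted 0.4). The share was higher in each of normal 2, normal 4 and diabetic 3 (20.4%, 22.9% and 18.9%) than in each of normal 3, diabetic 1 and diabetic 4 (18.6%, 15.6% and 17.1%). The list no longer passed without normal replicate 4 or diabetic replicate 1 (camera adjusted p = 0.158 and 0.0906) or with near-identical members removed (0.0734).

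The miR-30 family took 14.6% ± 1.07 of counts in diabetic and 9.61% ± 1.03 in normal ganglia (SD, n = 3), with no overlap (exact permutation p = 0.1, the smallest the design allows, adjusted 0.4). Its members went both ways. The 3 members past the threshold when adjusted over the list alone, against 0 over all miRNAs in edgeR, were miR-30a-5p, miR-30d-5p and miR-30e-5p (adjusted p = 0.0162, 0.0162 and 0.0207), with log2 fold changes of 0.85, 0.60 and 0.76, whereas miR-30c-1-3p had -0.45. These 3 are close paralogs that can share reads, so their values are uncertain and not independent of each other. As a set the family did not pass the directional test (camera adjusted p = 0.756), and it passed fry's test for change in either direction (adjusted p = 0.00929). miR-30a-5p was at 86380 ± 14860 CPM in diabetic and 48020 ± 11050 CPM in normal ganglia. It alone took 8.44% of counts in diabetic and 4.92% in normal ganglia. Its precursor lies on chromosome 1 (23272269 to 23272339).

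**Figure D2:**
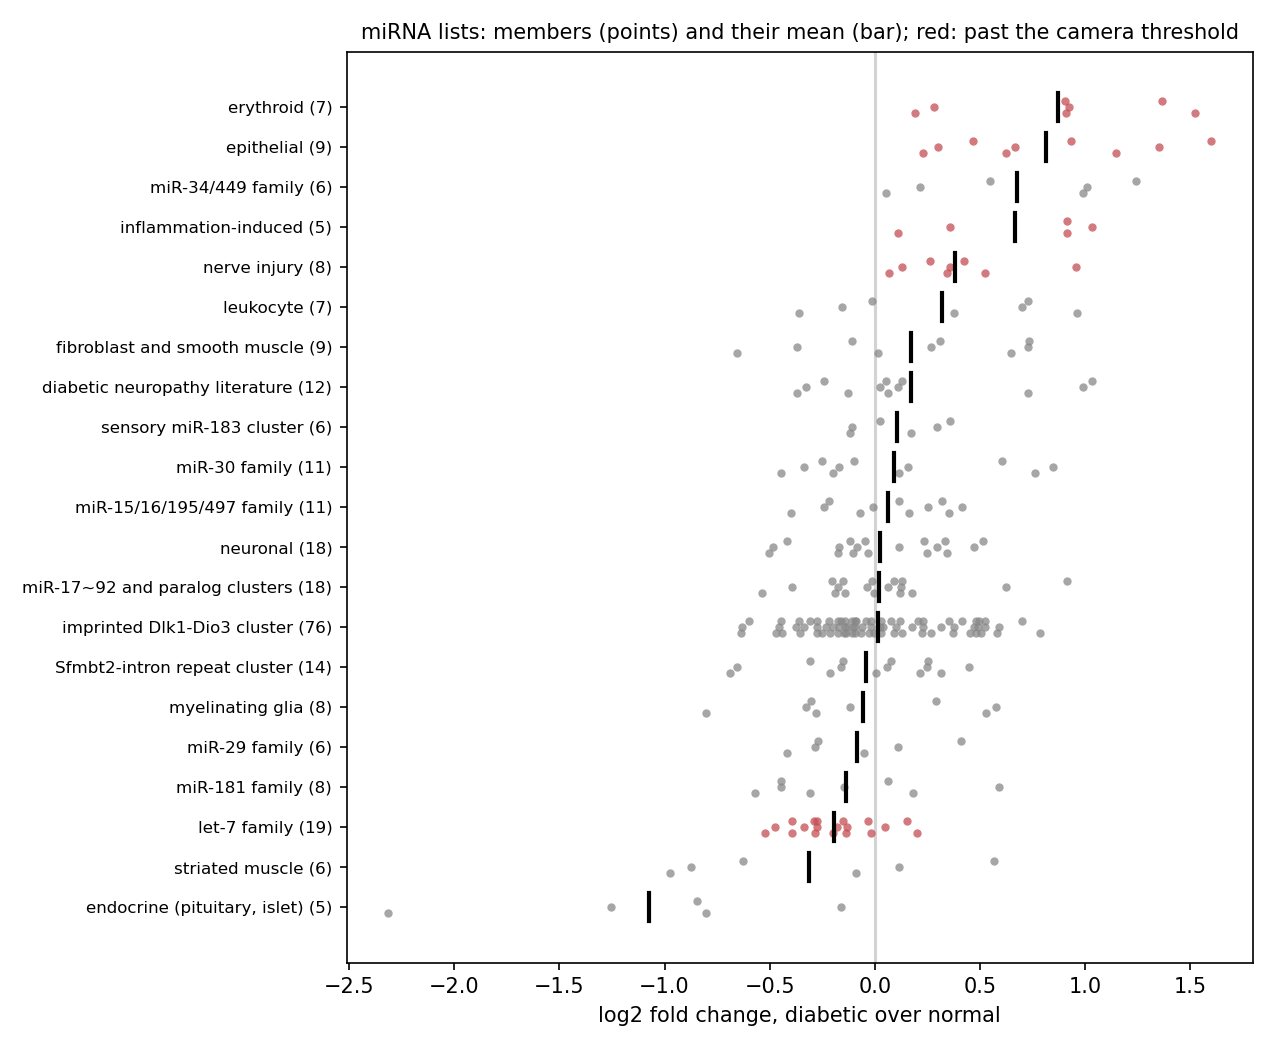
Log2 fold changes (diabetic over normal) of the tested members of 21 miRNA lists as points, with the mean of each list as a bar and the number of members in brackets. Red points belong to the 5 lists past the camera threshold, of which 4 are higher and 1 lower in diabetic ganglia. With an estimated correlation 0 lists pass.

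The lists of sensory neurons, neurons in general and myelinating glia did not pass. In the sensory miR-183 cluster, 4 of 6 members were positive (mean log2 fold change 0.10, camera adjusted p = 0.756), and miR-183-5p was at 49980 ± 14670 CPM in diabetic and 44370 ± 6283 CPM in normal ganglia. miR-96-5p and miR-182-3p had log2 fold changes of 0.29 and 0.36. In the neuronal list 8 of 18 members were positive (camera adjusted p = 0.756), with 0.52 for miR-218-5p and -0.42 for miR-384-5p. In the myelinating glia list 3 of 8 members were positive (mean log2 fold change -0.055, camera adjusted p = 0.496), with -0.30 for miR-338-3p, -0.33 for miR-204-5p and 0.29 for miR-204-3p. In edgeR no member of these 3 lists passed over all miRNAs or adjusted over the list alone.

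In the striated muscle list (mean log2 fold change -0.31, camera adjusted p = 0.288), miR-133b-3p and miR-133a-3p passed when adjusted over the list alone (adjusted p = 0.0275 and 0.0430), while 0 passed over all miRNAs in edgeR and miR-133b-3p did in DESeq2 (adjusted p = 0.0495). These paralogs share most of their sequence. The most abundant member, miR-1a-3p, went the other way, at 33940 ± 851 CPM in diabetic and 31290 ± 1367 CPM in normal ganglia, and miR-206-3p had a log2 fold change of 0.57. That of miR-499-5p, -0.97, rested on normal replicate 2 (47.1 CPM against 9.16 and 9.44 in the other normal libraries) and was 0.29 without it. The diabetic neuropathy literature list did not pass as a set (camera adjusted p = 0.581), with 1 of 12 members past the threshold adjusted over the list alone, miR-146a-5p, and 0 over all miRNAs in edgeR, where DESeq2, and edgeR at a mean of 100 counts or more, called miR-146a-5p. The list passed fry's test in either direction (adjusted p = 0.00632). The fibroblast and smooth muscle list did not pass (camera adjusted p = 0.547), with 0.65 for miR-143-3p and -0.65 for miR-199b-5p. The endothelial miR-126a-3p and miR-126a-5p had log2 fold changes of 0.11 and -0.23 and the hypoxia miRNA miR-210-3p had -0.27, and these lists were too small to test.

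The remaining lists did not pass camera, and in edgeR 0 of their members passed over all miRNAs or adjusted over the list alone. The adjusted p was 0.207 for the miR-34 and miR-449 family (all 6 positive, miR-34c-5p 0.99, or 0.20 without diabetic replicate 3), 0.288 for the miR-181 family, 0.547 for the miR-29 family and 0.889 for the miR-15, miR-16, miR-195 and miR-497 family. It was 0.775 for the miR-17~92 and paralog clusters, 0.756 for the imprinted Dlk1-Dio3 cluster with 76 tested members, and 0.775 for the Sfmbt2-intron repeat cluster. The miR-34 and miR-449 family passed without diabetic replicate 4 (0.0332) and the Sfmbt2-intron cluster without normal replicate 4 (0.0284). The miR-181 family and the nerve injury list passed fry's test in either direction (adjusted p = 0.00929 and 0.0396). The mean and the camera direction had opposite signs in the neuronal, miR-15 and miR-16, miR-17~92 and Dlk1-Dio3 lists, and the mean and the median in the neuronal, miR-30, miR-17~92, Dlk1-Dio3 and Sfmbt2-intron lists.

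The endocrine list, with miR-375-3p and miR-7 miRNAs of the pituitary and the pancreatic islet, had 5 of 5 negative log2 fold changes (mean -1.08, camera adjusted p = 0.0734), with 0 members past the threshold in edgeR over all miRNAs or adjusted over the list alone. The values rested on the library of normal replicate 3, in which miR-375-3p was at 5694 CPM, 15.6-fold the level of the other 5 libraries, and miR-7a-5p at 41830 CPM, 4.63-fold the level of the others. The counting intervals of miR-375-3p were 5760 to 5903 CPM before TMM scaling in that library and 246 to 272 CPM in normal replicate 2 (95% Wilson). Without normal replicate 3 the list had a camera adjusted p of 0.75 and miR-375-3p a log2 fold change of 0.46, whereas without normal replicate 2 or normal replicate 4 the list passed (0.00703 and 0.0284).

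**Figure D3:**
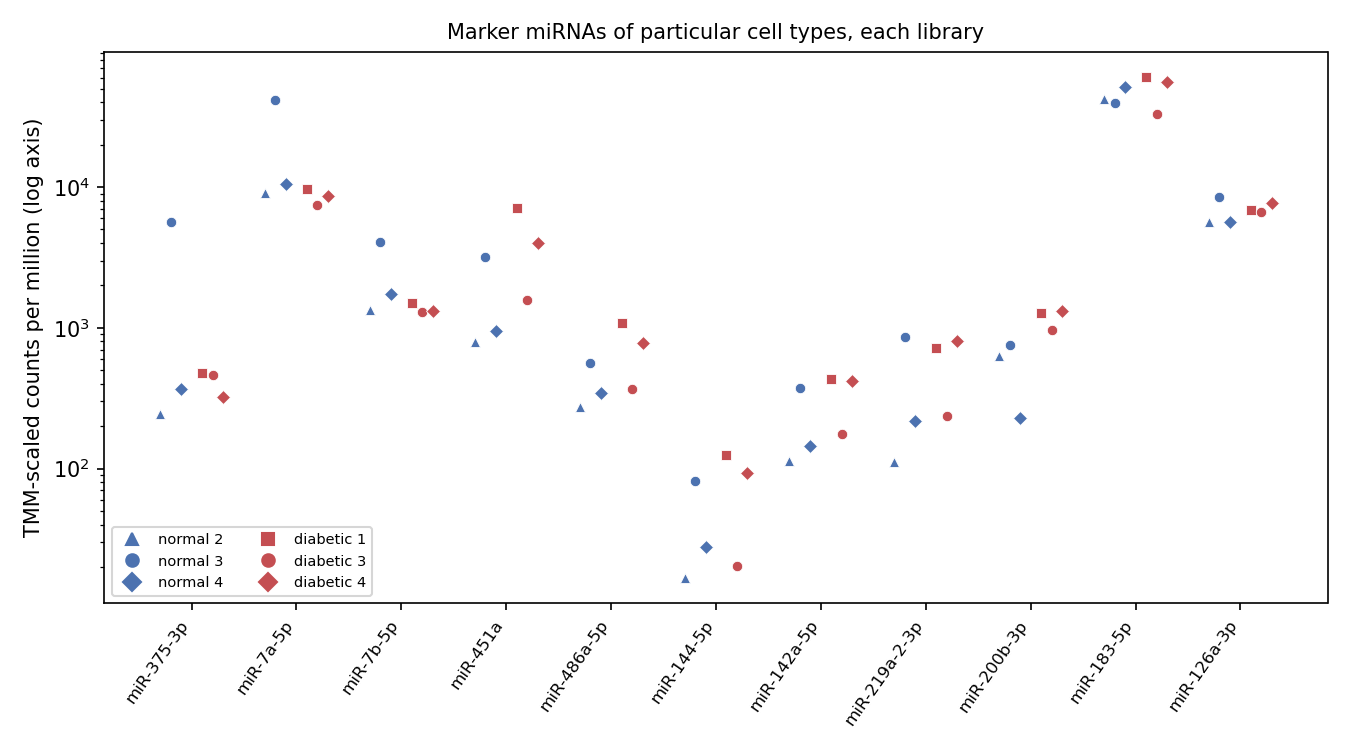
TMM-scaled CPM (log axis) of miRNAs typical of particular cell types, with a point per library. In normal replicate 3 miR-375-3p is at 5694 against 244 and 367 in the other normal libraries, and miR-451a ranges from 798 to 7104 over the 6 libraries.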

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

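Other handling of the precursor copies, edgeR without robust estimation and the shorter erythroid and let-7 lists were chosen after the data were seen. The pseudocounts and the filter meant for normalized values were not run because the table holds counts. The counts of 0 higher and 0 lower miRNAs in edgeR (55 at an unadjusted p under 0.05, and 104 without normal replicate 3) became 10 and 1 with DESeq2, 1 and 0 with a mean of 100 counts or more, and 31 and 13 with an unadjusted p and a fold of 1.5; they stayed at 0 and 0 with limma-voom, each other scaling or filter, either handling of copies and without any 1 library, and the adjusted p of miR-146a-5p ranged from 0.00245 (DESeq2) to 0.741 (replicate block). Numbers 3 and 4 are shared by the groups. Same-numbered libraries deviated together with correlations of -0.17 and 0.10, within the range of the other pairs (-0.21 to 0.28). So few pairs cannot show whether same-numbered libraries share more than a number. The replicate block draws the group difference from replicates 3 and 4 alone, since normal 2 and diabetic 1 have no same-numbered partner. Fewer calls and some turned signs can follow from that loss of libraries. With the replicate block there were 0 calls in either direction, 27 miRNAs at an unadjusted p under 0.05 against 55 without it, and 1 list higher (epithelial). Camera adjusted p-values were 0.0642 (inflammation-induced), 0.454 (erythroid), 0.118 (nerve injury), 0.134 (let-7) and 0.00447 (endocrine, lower). Log2 fold changes turned to -0.065 for miR-183-5p, 0.46 for miR-499-5p, -0.085 for miR-15b-5p and -0.018 for miR-195a-5p. The 4 lists higher and 1 lower became 0 and 0 with an estimated correlation (0.552 for inflammation-induced, 0.718 for epithelial, erythroid, nerve injury and let-7) and 1 and 0 by fry (0.388 for erythroid, nerve injury and let-7, 0.424 for epithelial). They became 2 and 0 with the shorter erythroid and let-7 lists (0.0554 for erythroid, 0.0734 for let-7). The nerve injury list kept its members there, and its adjusted p went to 0.0554 only through the adjustment over lists. Nerve injury had 0.105 without a count filter. With 1 library left out, 2 to 5 lists were higher and 0 to 2 lower, and adjusted p ranged from 0.000603 to 0.190 (erythroid), 0.0333 to 0.426 (nerve injury), 0.00392 to 0.158 (let-7), 0.00703 to 0.75 (endocrine), 0.0332 to 0.494 (miR-34 and miR-449) and 0.0284 to 0.886 (Sfmbt2-intron), while the inflammation-induced and epithelial lists passed each time. In the same fits log2 fold changes of miRNAs near 0 or resting on 1 library crossed 0: -0.15 to 0.16 (miR-99a-5p), -0.15 to 0.18 (let-7f-5p), -0.22 to 0.12 (miR-26a-5p), -0.28 to 0.10 (miR-183-3p), -1.36 to 0.29 (miR-499-5p), -0.45 to 0.23 (miR-126a-5p), -2.83 to 0.46 (miR-375-3p) and -0.98 to 0.026 (miR-669f-3p). The sign of miR-99a-5p also turned with DESeq2 and with its size factors (-0.017), limma-voom (-0.019), library totals (-0.065), upper quartile (-0.043), no count filter (-0.067) and the lowest copy (-0.0094), and that of let-7f-5p with library totals (-0.015) and no filter (-0.019). The number of miRNAs detected differed by 0.333 between the groups at 1 count or more and by 10.3 at 5 counts or more. Where no construction of the setting shows it, the cause was not tested. In simulated data at this depth, with 200 of 565 miRNAs changed, 18.2% of 1.5-fold changes were recovered. With fewer changed miRNAs the adjustment is stricter, so this share may be too high for these libraries.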

Other observations

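The edgeR values and list counts below come from tests fixed before the data were examined, while the tests on precursor arms, on the endocrine miRNAs and on miR-146a-5p were chosen, and what the splits would show was written down, only after the result had been seen. Across the precursors with both arms tested, the log2 fold changes of the 5p and the 3p arm were correlated (Spearman's rho 0.36, Pearson's r 0.45, each with permutation p = 0.0001, the smallest that the permutations can give). This correlation is across miRNAs, which are not independent replicates. In the miR-30 family, 3 members picked for their 5p values, miR-30a, miR-30d and miR-30e, had a mean log2 fold change of 0.74 for the 5p and -0.04 for the 3p arms, while miR-30b had -0.34 and 0.12. Among other miRNAs, miR-380-5p, miR-376b-3p, miR-494-3p and miR-379-5p of the Dlk1-Dio3 cluster had log2 fold changes of 0.79, 0.70, 0.58 and 0.41, each higher in all 3 diabetic libraries than in all 3 normal ones, with edgeR adjusted p between 0.241 and 0.377. In the same cluster 43 of 76 members were negative, among them miR-493-5p at -0.64, lower in all 3 diabetic libraries. In the miR-17~92 clusters, miR-19a-3p and miR-19b-3p had 0.91 and 0.62, miR-92b-5p and miR-20b-5p -0.53 and -0.39, and 10 of 18 members were negative.

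The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 0 miRNAs past the adjusted threshold, a count that 10 of the 10 splits reach by definition, so it tells nothing about chance, and the highest other count was 9. The real grouping gave 55 miRNAs at an unadjusted p under 0.05, reached by 2 splits, with 67 as the highest other, and 5 lists past the camera threshold, reached by 4 splits, with 6 as the highest other. The split of normal 2, normal 4 and diabetic 3 from the other 3 libraries gave the 9, 67 and 6, which points to a structure of the samples that the groups do not explain. Several blood miRNAs were lower in each of normal 2, normal 4 and diabetic 3 than in each of the other 3 libraries, with miR-451a at 798, 947 and 1576 against 3184, 7104 and 4009 CPM and miR-144-5p at most 27.9 against at least 81.5 CPM. miR-486a-3p of the erythroid list, the leukocyte miR-142a-3p and miR-223-5p and the glial miR-338-3p did not follow this split, whereas miR-142a-5p (at most 175 against at least 372 CPM) and miR-219a-2-3p (at most 235 against at least 723 CPM) did, and neither the source of this structure nor a biological explanation was tested.

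The endocrine miRNAs stood out in the library of normal replicate 3 alone. There the endocrine list without miR-7a-5p had a median log2 difference of 1.54 from the other 5 libraries, with 3.96 for miR-375-3p, 1.52 for miR-7b-5p and 0.28 for miR-7a-1-3p, against medians from -0.34 to -0.16 in the other libraries. The depth of that library does not account for this, since its total was 0.997 times that of normal replicate 4, where miR-375-3p was at 367 CPM. Pituitary tissue, which lies next to the ganglia, or other endocrine tissue in that library is a candidate source, and whether the reads of miR-375-3p in the other 5 libraries, at 244 to 479 CPM, came from the ganglion or from less of such tissue was not tested. A difference between individual mice stays open and was not tested.

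The higher values of miR-146a-5p and miR-146b-5p were set against 3 other explanations, tested on miR-146a-5p. For more leukocytes in the diabetic ganglia, miR-146a-5p was compared with the leukocyte list and exceeded its mean by 0.71 (SE 0.25) on the log2 scale. This gap cannot decide the question, since the SE rests on miRNAs as replicates, several of them arms of 1 precursor. The members also went both ways, from miR-142a-3p at 0.96, miR-223-5p at 0.73 and miR-142a-5p at 0.70 to miR-150-5p at -0.36, with 4 of 7 positive. For blood left in the tissue, the difference between the groups was 1.11 (SE 0.12) with miR-451a as a covariate and 1.04 without. Over these 6 libraries this argues against an effect that follows red blood cells. The fit cannot speak to leukocytes left from blood, since miR-451a marks red cells. The scaling between libraries left a log2 fold change of at least 0.97 in each of 4 scalings. Diabetes itself, including an entry or activation of some leukocytes, stays open and was not tested, and edgeR as first chosen did not pass miR-146a-5p over all miRNAs.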
